A study of Mus musculus with 12 samples.

How the data were processed

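Ly6G-positive mature neutrophils from mouse bone marrow were kept for 6 h at 37C with 5 µM CpG-B or without it, per the sample labels, which call the second condition vehicle in one place and untreated in another. PolyA RNA was sequenced on an Illumina HiSeq instrument at BGI Genomics, per the submitters. Wild-type and Rab27a knockout animals carry the strain label C57BL/6. The Rab27a allele, the sex and number of animals, the strandedness of the libraries and the alignment rate are not given in the sources used here.

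Estimated counts (RSEM expected counts per RefSeq transcript) were made by the authors and are used as deposited, without scaling. TPM values were scaled by the authors to a fixed sum per library before deposit, per the file headers, and were not used in any test here. FPKM values were scaled by the authors for transcript length and library size, per the file headers, and were not used here. Per the submitters' processing notes the tools were Bowtie2 (version not stated) and RSEM 1.2.28 with genome build GRCm39, with no roles or order given. Filters and pooling of lanes are not given in the sources used here.

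Each library had 54716 transcripts (24908 curated, 29808 predicted), and 47.4% of the estimated counts were not whole numbers. Counts were summed over the transcripts of each NCBI gene and rounded. This gave 15986 genes, of which 15883 matched a symbol, and the 103 unmatched held at most 0.101% of counts. Gene names and gene order came from the RefSeq annotation of the mouse assembly GRCm38.p6, an earlier build than GRCm39, so only names and neighbours were taken from it. Counts per library numbered 1, 2 and 3 were 11444586, 13075096 and 12580018 (unstimulated wild-type), 13164438, 12684861 and 11847329 (wild-type with CpG), 10991524, 11464054 and 10928813 (unstimulated knockout) and 12738590, 15513279 and 12313777 (knockout with CpG). The 10 most abundant genes held 9.3 to 12.5% of counts.

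Genes were kept by filterByExpr with the 4 groups (smallest count 10, smallest total 15), which left 10802. TMM factors ran from 0.900 to 1.093. A quasi-likelihood negative binomial model with one mean per group was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3), leaving 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison. The common dispersion was 0.0293, a coefficient of variation of 17.1%, and the median prior degrees of freedom were 5.32. The 5 comparisons were CpG against unstimulated in each genotype, knockout against wild-type in each treatment, and their interaction. Standard errors are those of the log2 fold change from the fitted model. Ratios of genes with few counts carry intervals from the counts alone, and a ratio to 0 counts is given as a floor computed with 3 counts in each library.

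Named genes were Rab27a, the 5 highest and 5 lowest log2 fold changes among called genes with a mean of at least 5 CPM over the libraries compared and no overlap between groups, up to 2 members of each list tied to the question and 1 of each other list, and a short set of inflammatory and granule genes named in advance. A few genes that this rule picks are not reported here. The comparisons, filter, test, lists and naming rule were fixed before the data were examined.

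The 18 function lists (cytokines, chemokines, NF-kB pathway and feedback, interferon-stimulated, TLR9 and nucleic acid sensing, other receptors, Rab27 effectors and exocytosis, endolysosomal trafficking, primary granule, secondary and tertiary granule, NADPH oxidase, apoptosis, cell cycle, glycolysis and hypoxia, stress response, immediate early, antigen presentation, lipid mediators) and 12 marker lists were written from general knowledge. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the function lists, and separately over the marker lists, of a comparison. Mitochondrially encoded genes and Xist were not analysed here. Camera with an estimated correlation, fry and camera with replicate number as a block were run beside it.

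Alternatives tried were scaling by library size alone and by relative log expression, DESeq2 1.42.0, a filter of 1 CPM in 3 libraries, no filter, a robust quasi-likelihood fit, a fit of only the libraries compared, replicate number as a block, animal (genotype and number together) as a block, fixed in edgeR for the CpG effects and the interaction and random in limma voom for the genotype effects, a 2-fold threshold and leaving out each library. Fits without both knockout libraries numbered 1 or 3 and the tests by gene order near Rab27a were added after the data were seen.

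Replicate numbers were examined for pairing by correlating residuals of log CPM (prior count 1) within groups. Same-numbered wild-type libraries correlated at 0.28, 0.41 and 0.44, all above the threshold of 0.1 set in advance, so blocked values are given beside wild-type results. Same-numbered knockout libraries gave 0.62, 0.09 and 0.68, below the threshold for number 2. Between genotypes same-numbered libraries correlated at -0.14 to 0.03, and no pairing was used there. Replicate number as a block fits an effect per number that both genotypes share. Only animal as a block models pairs within a genotype.

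In a self-test 200 genes were changed in simulated counts, drawn independently for each library. Of changes of 1.5, 2, 4 and 8 fold, 20, 60, 92 and 98% were recovered for CpG in wild-type cells, 14, 50, 88 and 100% for CpG in the knockout, 18, 56, 90 and 100% for genotype without CpG, 30, 62, 92 and 100% for genotype with CpG, and 8, 26, 76 and 94% for the interaction. False calls made up 2.3 to 8.9% of calls. Libraries of a group were no copies of each other (chi-square per degree of freedom 7.39 to 46.1). The first 3 principal components held 31.2, 28.6 and 14.8% of variance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.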

Results

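Mature mouse bone-marrow neutrophils, isolated by positive selection for Ly6G, were compared between wild-type and Rab27a knockout animals after 6 h with or without 5 µM CpG-B, a TLR9 ligand. Each of the 4 groups had 3 libraries, and 10802 genes were tested across all 12. Rab27a encodes a small GTPase that docks granules and other secretory organelles at the plasma membrane. Per-gene counts are the deposited estimated counts, and levels are scaled to library size (CPM) and given as mean ± SD of 3 libraries. Log2 fold changes carry their standard error (SE). A gene is said to rise, fall or change at an adjusted p of at most 0.05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Whether replicates of a group came from separate animals is not given in the sources used here beyond their numbers, so p-values measure the spread between these samples, which may be technical.

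Rab27a itself was lower in every knockout library than in any wild-type library. It stood at 272 ± 54.9 CPM in unstimulated and 236 ± 42.9 CPM in CpG-treated wild-type cells, against 113 ± 17.4 and 107 ± 9.78 CPM in the knockout. The difference was 2.4-fold in unstimulated cells (log2 -1.26, SE 0.17; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000365) and 2.2-fold with CpG (log2 -1.14, SE 0.17; adjusted p = 0.00112). CpG did not change it in either genotype (adjusted p = 0.659 and 0.862 by the same edgeR test). The counts sum all its transcripts, and the deleted part of the gene is not given in the sources used here.

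**Figure D1:**
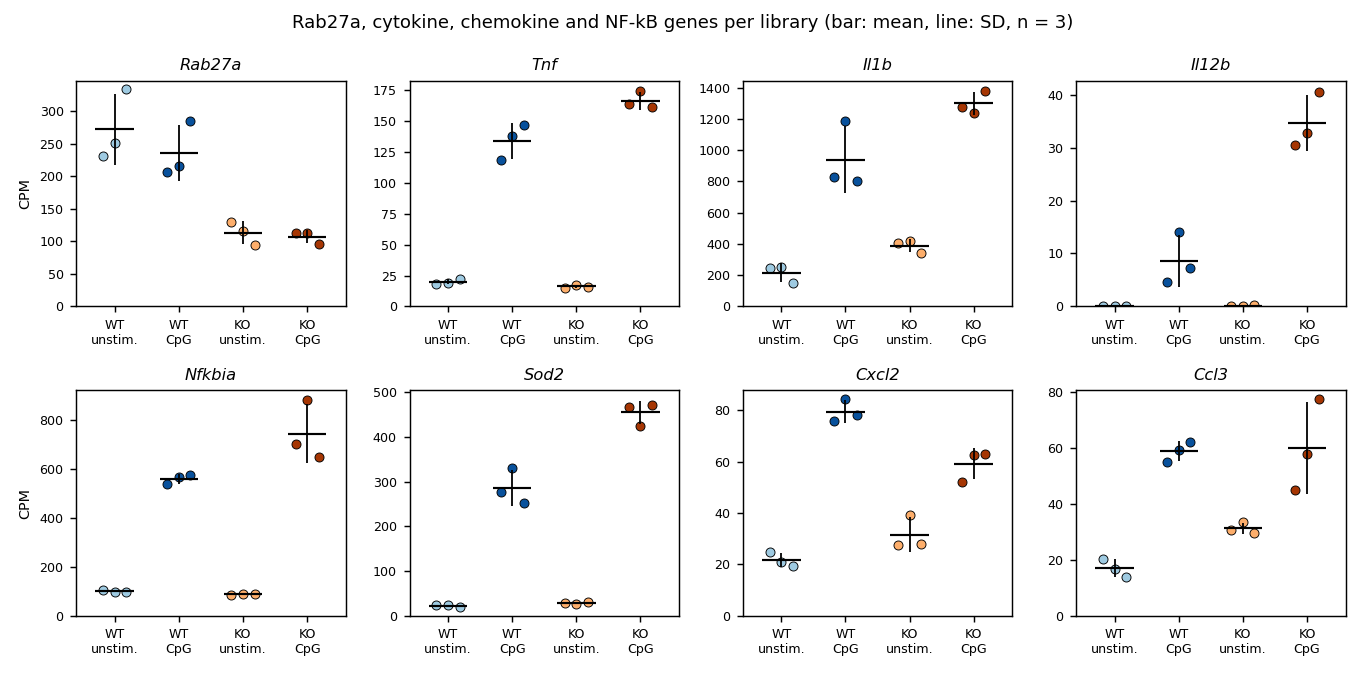
CPM of Rab27a, Tnf, Il1b, Il12b, Nfkbia, Sod2, Cxcl2 and Ccl3 per library in the 4 groups (bar: mean, line: SD, n = 3). Rab27a falls from 272 CPM in unstimulated wild-type cells to 113 CPM in the knockout, Tnf rises with CpG in both genotypes, and Il12b with CpG is higher in the knockout (34.6 against 8.63 CPM).

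In wild-type neutrophils CpG raised cytokine and NF-kB genes by 6 h. Of 10802 genes, 512 rose and 140 fell, 316 of them by at least 2-fold. The cytokine gene Tnf rose 6.76-fold, from 19.8 ± 2.02 to 134 ± 14.5 CPM (log2 2.76, SE 0.12), and Il1b rose 4.35-fold, from 216 ± 59.1 to 939 ± 216 CPM (log2 2.12, SE 0.21). Sod2, the mitochondrial superoxide dismutase and an NF-kB target, rose 12.7-fold (log2 3.66, SE 0.13). Adjusted p was 1.29e-08 for Tnf, 2.02e-05 for Il1b and 4.54e-09 for Sod2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

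Among genes averaging at least 5 CPM over the wild-type libraries, the highest fold changes in wild-type cells belonged to the interferon-inducible chemokine gene Cxcl10 (log2 5.67, SE 0.64), the transporter-family gene Mfsd7a (4.85, SE 0.37), Lacc1, an enzyme of purine nucleoside metabolism in phagocytes (4.78, SE 0.36), the adhesion molecule gene Icam1 (4.57, SE 0.23) and the kinase gene Ikbke (4.42, SE 0.22). The lowest were the integrin subunit gene Itgb5 (log2 -1.43, SE 0.33), the tetraspanin gene Tspan13 (-1.28, SE 0.20), the RNA-binding protein gene Igf2bp2 (-1.25, SE 0.31), the ubiquitin ligase gene Trim6 (-1.23, SE 0.33) and the TNF-family ligand gene Tnfsf14 (-1.12, SE 0.22). In edgeR's test, without 1 wild-type library the adjusted p of Itgb5 reached 0.102 (unstimulated 2), that of Igf2bp2 0.132 (CpG 1) and that of Trim6 0.158 (CpG 2).

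Cytokine genes were mostly higher in wild-type cells: 11 of 21 rose, 1 fell and 9 did not pass (adjusted over the list alone, 12 rose and 2 fell, camera adjusted p = 2.45e-15). Il12b, a subunit of IL-12 and IL-23, came from almost no counts and was 109 times higher after CpG (interval 37 to 532), and the anti-inflammatory cytokine gene Il10 was 51.8 times higher (14 to 433). These intervals, and every floor given for a gene with few counts, cover counting error only. Il6, another NF-kB-driven cytokine gene, rose from 0.232 ± 0.221 to 1.35 ± 0.448 CPM (log2 2.47, SE 0.64; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0355). Its adjusted p was 0.0523 in edgeR with replicate number as a block, and 0.158 without wild-type CpG 2. With animal as a block, which pairs the wild-type libraries, the call held.

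Chemokine genes gave 9 rises and 1 fall among 13 (adjusted over the list alone, 11 rose and 1 fell, camera adjusted p = 1.34e-16). Cxcl2, a neutrophil attractant, rose from 21.7 ± 2.9 to 79.5 ± 4.46 CPM (log2 1.87, SE 0.15), and Ccl3, an attractant of monocytes and lymphocytes, from 16.9 ± 3.18 to 58.8 ± 3.69 CPM (log2 1.80, SE 0.18). Of 29 NF-kB pathway and feedback genes, 25 rose and none fell (adjusted over the list alone, 27 rose, camera adjusted p = 1.23e-110). Among them Nfkbia, which encodes the inhibitor that ends NF-kB signalling, rose from 100 ± 3.29 to 559 ± 19.9 CPM (log2 2.48, SE 0.12).

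All 36 interferon-stimulated genes had higher estimates after CpG in wild-type cells, and 19 rose (adjusted over the list alone, 34 rose, camera adjusted p = 1.75e-20, and adjusted p = 0.174 with an estimated correlation). Examples are the DNA-binding PYHIN gene Ifi204 (log2 2.13, SE 0.26), the poly-ADP-ribosyltransferase gene Parp14 (1.90, SE 0.25) and the antiviral gene Ifit1 (2.32, SE 0.50; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0119). Without unstimulated wild-type 2 the edgeR adjusted p of Ifit1 was 0.0697.

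TLR9 and nucleic acid sensing genes gave 7 rises and 1 fall among 35 (adjusted over the list alone, 9 rose and 1 fell, camera adjusted p = 0.0401, and adjusted p = 0.174 with an estimated correlation). The camera adjusted p was 0.0524 with replicate number as a block. Tlr9 itself, the receptor of CpG DNA, rose from 3.35 ± 0.661 to 9.01 ± 0.608 CPM (log2 1.42, SE 0.23), the transcription factor gene Irf5 rose 2.14-fold (log2 1.10, SE 0.11) and the signalling adaptor gene Traf3 2.14-fold (log2 1.09, SE 0.13). Unc93b1, the chaperone that carries TLR9 to endosomes, did not pass (log2 0.27, SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.249), but had an adjusted p of 0.0356 in edgeR with animal as a block.

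Other pattern recognition and surface receptor genes gave 10 rises and 1 fall among 31 (adjusted over the list alone, 11 rose and 3 fell, camera adjusted p = 6.89e-05, and adjusted p = 0.174 with an estimated correlation), with the lipopolysaccharide co-receptor gene Cd14 up 4.83-fold (log2 2.27, SE 0.22). Antigen presentation and costimulation genes gave 7 rises among 17 (adjusted over the list alone, 8 rose, camera adjusted p = 2.02e-08), including the checkpoint ligand gene Cd274 (log2 1.23, SE 0.16). Apoptosis and survival genes gave 7 rises among 21 (adjusted over the list alone, 8 rose, camera adjusted p = 1.14e-08), including the death receptor gene Fas (log2 1.71, SE 0.12). Stress response genes gave 4 rises among 20 (adjusted over the list alone, 5 rose, camera adjusted p = 0.00123, and adjusted p = 0.174 with an estimated correlation), led by the autophagy receptor gene Sqstm1 (log2 1.26, SE 0.17). Immediate early genes gave 4 rises among 18 (adjusted over the list alone, 7 rose, camera adjusted p = 0.00191, and adjusted p = 0.268 with an estimated correlation), led by the nuclear receptor gene Nr4a1 (log2 1.53, SE 0.21).

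NADPH oxidase genes gave 3 rises among 8 in wild-type cells (adjusted over the list alone, 4 rose, camera adjusted p = 0.0401, and adjusted p = 0.412 with an estimated correlation). That camera value was 0.0524 with replicate number as a block. Cybb, the catalytic subunit, rose from 746 ± 90.6 to 1140 ± 93.8 CPM (log2 0.62, SE 0.13) and Hvcn1, the proton channel that sustains the burst, rose by log2 0.67 (SE 0.16). In edgeR's test the adjusted p was 0.0557 for Cybb without unstimulated wild-type 1 and 0.13 for Hvcn1 without wild-type CpG 2.

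In wild-type cells camera called none of the lists of exocytosis, endolysosomal trafficking and granule genes. None of 18 Rab27 effector and exocytosis genes passed (camera adjusted p = 0.396), and the Rab GTPase regulator gene Madd had a log2 change of -0.30 (SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.174; 0.00972 with animal as a block). Of 34 endolysosomal trafficking genes 2 rose (adjusted over the list alone, 4 rose, camera adjusted p = 0.302): Tfe3, a lysosomal transcription factor gene (log2 0.69, SE 0.11), and Rab32, a GTPase of lysosome-related organelles (log2 0.49, SE 0.11, edgeR adjusted p = 0.103 without wild-type CpG 2). None of 11 primary granule genes passed (camera adjusted p = 0.844; median 0.08 and mean 0.05, with the test pointing down), including Mpo (log2 -0.36, SE 0.71) and the lysosomal glucuronidase gene Gusb (-0.34, SE 0.14, edgeR adjusted p = 0.221, and 0.0249 with animal as a block). Among 16 secondary and tertiary granule genes 1 rose and 1 fell (adjusted over the list alone, the same counts, camera adjusted p = 0.672): the haemoglobin scavenger gene Hp (log2 0.70, SE 0.18, edgeR adjusted p = 0.129 without unstimulated wild-type 1) and the metalloprotease gene Adam8 (log2 -0.61, SE 0.12). The gelatinase gene Mmp9 did not pass (log2 -0.13, SE 0.23).

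None of 22 cell cycle genes passed (camera adjusted p = 0.164). Glycolysis and hypoxia genes gave 2 rises among 22 (adjusted over the list alone, 2 rose, camera adjusted p = 0.768; mean 0.02 and median -0.14, with the test pointing down), led by Acod1, which makes itaconate (log2 2.74, SE 0.25). Lipid mediator genes gave 1 rise among 12 (adjusted over the list alone, 2 rose, camera adjusted p = 0.814; median -0.18 and mean 0.05), the prostaglandin E synthase gene Ptges (log2 1.72, SE 0.18). Of 12 mature neutrophil markers 1 rose, the transcription factor gene Mxd1 (log2 0.60, SE 0.13, edgeR adjusted p = 0.058 without unstimulated wild-type 2; camera adjusted p = 0.967 for the list). Of 17 monocyte and macrophage markers 3 rose (adjusted over the list alone, 3 rose and 1 fell, camera adjusted p = 0.0434, and adjusted p = 0.989 with an estimated correlation), with the growth factor receptor gene Csf1r at 197 ± 11.9 and 550 ± 28.1 CPM.

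With animal as a block, which pairs the same-numbered wild-type libraries, the wild-type CpG count was 1824, with 1051 higher and 773 lower, so how far rises outnumber falls depends on the fit. DESeq2 gave 598 higher and 234 lower, and scaling by library size alone 492 higher and 224 lower. The count was 425 without unstimulated wild-type 1 and 432 without wild-type CpG 2.

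In knockout neutrophils CpG raised 818 genes and lowered 439, 553 of them by at least 2-fold. Tnf rose 10.3-fold, from 16.2 ± 1.19 to 167 ± 7.06 CPM (log2 3.36, SE 0.12). Il1b rose 3.34-fold, from 390 ± 42.2 to 1300 ± 73.3 CPM (log2 1.74, SE 0.20), and Sod2 15.8-fold (log2 3.98, SE 0.13). Adjusted p was 2.17e-09 for Tnf, 5.93e-05 for Il1b and 1.72e-09 for Sod2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling by library size alone gave 739 higher and 778 lower, and 818 genes in all were called without unstimulated knockout 2.

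Among genes averaging at least 5 CPM, the highest fold changes in the knockout were those of Il12b, 392 times higher (interval 134 to 1900), Cxcl10 (log2 7.15, SE 0.65), the phosphodiesterase gene Smpdl3b, which restrains TLR signalling (6.31, SE 0.24), Ikbke (5.54, SE 0.24) and Icam1 (5.53, SE 0.25). Among the lowest were the inhibitory-receptor-family gene Cd300ld4 (log2 -1.85, SE 0.41), the thrombomodulin gene Thbd (-1.66, SE 0.28), the microtubule-associated gene Eml1 (-1.59, SE 0.28) and the chemokine receptor gene Cxcr3 (-1.57, SE 0.37; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0127, and 0.0657 without unstimulated knockout 1). Cd300ld4 has near-identical copies in the mouse genome, so how its shared reads were divided is uncertain.

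Of the 21 cytokine genes 9 rose and 3 fell in the knockout (adjusted over the list alone, 12 rose and 4 fell, camera adjusted p = 2.74e-08, and adjusted p = 0.0774 with an estimated correlation). Il10 was 26.2 times higher (interval 8.67 to 129), and Il6 did not pass (log2 1.72, SE 0.54; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0564). Of the 13 chemokine genes 7 rose and 1 fell (adjusted over the list alone, 9 rose and 1 fell, camera adjusted p = 5.22e-07, and adjusted p = 0.0774 with an estimated correlation). Ccrl2, an atypical chemokine receptor gene, rose 6.05-fold (log2 2.60, SE 0.26), Cxcl2 rose from 31.6 ± 6.74 to 59.2 ± 6.11 CPM (log2 0.91, SE 0.15) and Ccl3 from 31.2 ± 2.04 to 59.9 ± 16.4 CPM (log2 0.94, SE 0.18).

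NF-kB pathway and feedback genes rose in 27 of 29 cases (adjusted over the list alone, 27 rose and 1 fell, camera adjusted p = 1.59e-98), with Nfkbia up 8.51-fold (log2 3.09, SE 0.12). Interferon-stimulated genes rose in 33 of 36 cases (adjusted over the list alone, 36 rose, camera adjusted p = 1.57e-30, and adjusted p = 0.0774 with an estimated correlation). Parp14 rose 7.04-fold (log2 2.82, SE 0.26), Ifi204 6.45-fold (log2 2.69, SE 0.27) and Ifit1 10.9-fold (log2 3.44, SE 0.52).

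TLR9 and nucleic acid sensing genes gave 9 rises and 1 fall in the knockout (adjusted over the list alone, 9 rose and 4 fell, camera adjusted p = 0.00332, and adjusted p = 0.0774 with an estimated correlation). Tlr9 rose from 3.11 ± 0.96 to 10 ± 1.24 CPM (log2 1.68, SE 0.23), Irf5 2.88-fold (log2 1.53, SE 0.11) and Traf3 2.8-fold (log2 1.49, SE 0.13). Unc93b1 rose from 143 ± 10.4 to 199 ± 31.3 CPM (log2 0.48, SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0133, and 0.0745 without unstimulated knockout 3).

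Other pattern recognition and surface receptor genes gave 10 rises and 3 falls (adjusted over the list alone, 10 rose and 4 fell, camera adjusted p = 0.000738, and adjusted p = 0.252 with an estimated correlation), led by the C-type lectin gene Clec4e (log2 1.57, SE 0.12). Antigen presentation and costimulation genes gave 10 rises and 1 fall (adjusted over the list alone, 12 rose and 1 fell, camera adjusted p = 3.79e-09), with the MHC class I light chain gene B2m at 573 ± 69.3 and 1350 ± 73.8 CPM (log2 1.24, SE 0.14). Apoptosis and survival genes gave 7 rises (adjusted over the list alone, 7 rose and 1 fell, camera adjusted p = 1.6e-07), with Fas up 4.63-fold (log2 2.21, SE 0.12). NADPH oxidase genes gave 5 rises among 8 (adjusted over the list alone, 5 rose and 1 fell, camera adjusted p = 0.000866, and adjusted p = 0.205 with an estimated correlation), among them Cybb (log2 1.17, SE 0.13) and the cytosolic subunit gene Ncf4 (0.68, SE 0.11).

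Of the Rab27 effector and exocytosis genes 1 rose and 1 fell (adjusted over the list alone, the same counts, camera adjusted p = 0.559). Madd fell by 0.46 log2 units (SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0156, and 0.0948 without unstimulated knockout 2), and the vesicle fusion gene Vamp7 rose by 0.64 (SE 0.19, edgeR adjusted p = 0.0415, and up to 0.17 without unstimulated knockout 3, with the call lost in 9 of 12 such fits). Endolysosomal trafficking genes gave 4 rises (adjusted over the list alone, 4 rose, camera adjusted p = 0.918; median -0.04 and mean 0.03), with Tfe3 at log2 0.92 (SE 0.11) and Rab32 at 0.68 (SE 0.11). Primary granule genes gave 1 fall, Gusb (log2 -0.75, SE 0.14; adjusted over the list alone, 1 fell, camera adjusted p = 0.644). Mpo did not pass, at 103 ± 107 and 77.8 ± 69.5 CPM. Secondary and tertiary granule genes gave 3 rises and 1 fall (adjusted over the list alone, the same counts, camera adjusted p = 0.372), with Hp at log2 1.35 (SE 0.18) and Adam8 at -0.82 (SE 0.12), while Mmp9 did not pass (0.12, SE 0.23).

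None of the cell cycle genes passed in the knockout (camera adjusted p = 0.696). Glycolysis and hypoxia genes gave 2 rises (adjusted over the list alone, 2 rose, camera adjusted p = 0.227), with Acod1 at log2 2.71 (SE 0.25). Stress response genes gave 4 rises and 1 fall (adjusted over the list alone, 4 rose and 2 fell, camera adjusted p = 0.13), with Sqstm1 at log2 1.22 (SE 0.17). Fry, run beside camera, called that list higher (fry adjusted p = 0.0463). Immediate early genes gave 3 rises and 1 fall (adjusted over the list alone, 4 rose and 1 fell, camera adjusted p = 0.559), with the AP-1 gene Junb at log2 1.06 (SE 0.17). Lipid mediator genes gave 1 rise and 1 fall (adjusted over the list alone, the same counts, camera adjusted p = 0.918), with Ptges at log2 2.51 (SE 0.19). Monocyte and macrophage markers gave 4 rises among 17 (adjusted over the list alone, 4 rose, camera adjusted p = 0.00337, and adjusted p = 0.972 with an estimated correlation), with Csf1r at 169 ± 13 and 851 ± 138 CPM.

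Single markers of other cells also moved in the knockout with CpG. The T cell gene Cd8a rose from 0.199 ± 0.267 to 2.63 ± 2.38 CPM (log2 3.62, SE 0.91; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0185, and 0.0855 without knockout CpG 3), and the dendritic cell gene Zbtb46 from 0.387 ± 0.197 to 2.05 ± 0.189 CPM (log2 2.38, SE 0.58, edgeR adjusted p = 0.0156, and 0.0902 without unstimulated knockout 2). The eosinophil gene Siglecf fell from 8.62 ± 0.62 to 4.64 ± 0.528 CPM (log2 -0.89, SE 0.17). Of 12 mature neutrophil markers 2 rose, with Mxd1 at log2 0.79 (SE 0.13). No other marker list passed with CpG, with camera adjusted p of at least 0.924 in the knockout and 0.967 in wild-type cells.

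The genes that CpG moved overlapped widely between the genotypes, which share no library. In both genotypes 475 genes rose (38.8 expected by chance) and 107 fell (5.7 expected), and no gene was called in opposite directions. Log2 fold changes correlated across all tested genes (r = 0.78), although genes are not independent replicates. With an estimated correlation between genes, the list calls that held were those of cytokines and chemokines in wild-type cells, and of NF-kB, apoptosis and antigen presentation genes in both genotypes. No list call held in the genotype comparisons or the interaction.

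No gene had a CpG response that differed between genotypes at an adjusted p of 0.05 in edgeR's quasi-likelihood interaction test without a block. At an unadjusted p of 0.05 there were 365 genes where 540 were expected, and DESeq2 called 2. Fits without a block leave differences between same-numbered pairs in the spread, so the low count does not show that the responses were equal. With animal as a block in edgeR there were 1199 genes at an unadjusted p of 0.05, and 13 passed (6 positive and 7 negative). In a self-test with simulated changes edgeR recovered 26% of 2-fold and 76% of 4-fold interaction changes. The heme synthesis gene Alas1 came closest (log2 1.02, SE 0.17, edgeR adjusted p = 0.562, and 0.0408 with animal as a block; DESeq2 adjusted p = 0.00083), and DESeq2 also called Csf1r (log2 0.85, SE 0.18, edgeR adjusted p = 0.931; DESeq2 adjusted p = 0.0156).

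By estimate alone, the interaction was positive for Smpdl3b (log2 1.91), Gbp2, a guanylate-binding protein gene (1.83, SE 0.50), Ifit1 (1.12, SE 0.69), Nfkbia (0.61, SE 0.16), Tnf (0.60, SE 0.16), Cybb (0.56, SE 0.18) and Irf5 (0.43, SE 0.16). It was negative for the C-type lectin gene Clec4n (-1.22, SE 0.35), Cxcl2 (-0.96, SE 0.21), Ccl3 (-0.85, SE 0.25) and Il1b (-0.38, SE 0.28). None of these passed without a block, and of them Clec4n passed with animal as a block (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0494). Across the 537 genes with a mean CpG effect of at least 2-fold, the median response was larger in the knockout by 0.38 log2 units, and 113 of them (21%) responded less there. The 470 genes raised by CpG had a median of 0.39 and the 67 lowered had 0.29. Among genes chosen by the wild-type CpG effect alone the medians were 0.34 for 292 raised and -0.03 for 24 lowered genes, 12 of these responding less in the knockout. The median SE of a single gene was 0.46.

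**Figure D2:**
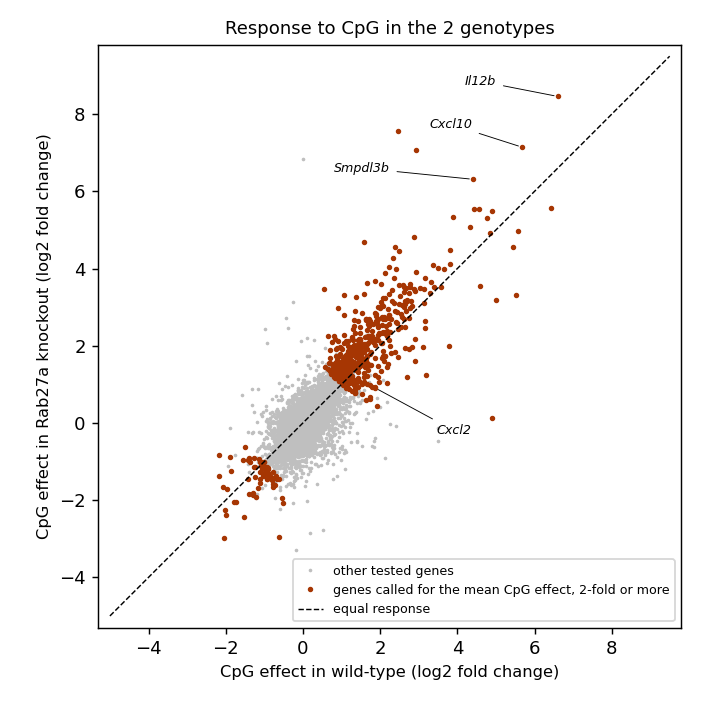
Log2 fold change with CpG in wild-type (x axis) and Rab27a knockout (y axis) neutrophils for all tested genes, with the 537 genes of at least 2-fold mean CpG effect in colour. Most lie above the dashed line of equal response, Smpdl3b among them, while Cxcl2 lies below it (1.87 against 0.91).

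Unstimulated knockout neutrophils differed from wild-type cells in 513 genes, 228 higher and 285 lower, 268 of them by at least 2-fold. Besides Rab27a, the cytokine gene Il18 was 5.46-fold higher, at 30.6 ± 6.69 against 5.61 ± 1.05 CPM (log2 2.45, SE 0.27). Il18 lies within 200 tested genes of Rab27a in the gene order. The heme-degrading enzyme gene Hmox1 was 2.12-fold lower, at 235 ± 21.3 against 498 ± 65.4 CPM (log2 -1.08, SE 0.14). Adjusted p was 6.85e-05 for Il18 and 0.000234 for Hmox1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

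Among genes averaging at least 5 CPM, the highest were the kallikrein gene Klk1b22 (at least 43.8-fold), the histidine-degrading enzyme gene Hal (log2 5.34, SE 0.34), the T cell receptor complex gene Cd3d (4.91, SE 0.30), the ubiquitin-ligase-family gene Trim34b (4.89, SE 0.33) and the RNA methylthiotransferase gene Cdk5rap1 (4.05, SE 0.23). Among the lowest were Trim12a, another TRIM-family gene, at 0.345 ± 0.314 against 244 ± 46.5 CPM (log2 -9.39, SE 0.36), the zinc finger gene Zbtb44 (410 times lower, interval 140 to 1990), the beta-globin gene Hbb-bt at 2 ± 2.19 against 388 ± 73.9 CPM (log2 -7.56, SE 0.64) and the actin-regulator gene Eps8l1 (213 times, 58.7 to 1770). Klk1b22, Trim34b, Trim12a and Hbb-bt have near-identical copies, so their values depend on how shared reads were divided and are uncertain.

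Cytokine genes were higher in unstimulated knockout cells, 4 of 21 passing and none falling (adjusted over the list alone, 5 rose, camera adjusted p = 0.000807, and adjusted p = 0.648 with an estimated correlation). Il1b was 1.8-fold higher (log2 0.85, SE 0.20; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0253, and 0.113 without unstimulated knockout 2), as was the macrophage growth factor gene Csf1 (0.84, SE 0.20, edgeR adjusted p = 0.0249, and 0.107 without unstimulated wild-type 3). Tnf (log2 -0.29, SE 0.12) and Il6 (1.54, SE 0.69) did not pass, with edgeR adjusted p of 0.22 and 0.267. Chemokine genes gave 1 rise (adjusted over the list alone, 3 rose, camera adjusted p = 0.0365, and adjusted p = 0.648 with an estimated correlation): Ccl3, at log2 0.88 (SE 0.18, edgeR adjusted p = 0.0125, and 0.0644 without unstimulated knockout 2). Cxcl2 did not pass (0.54, SE 0.15, edgeR adjusted p = 0.0624).

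Immediate early genes gave 2 rises among 18 (adjusted over the list alone, 5 rose, camera adjusted p = 0.000807, and adjusted p = 0.648 with an estimated correlation), including the AP-1 gene Jund (log2 0.73, SE 0.14). NF-kB genes gave 1 rise, the phosphatase gene Dusp1 (log2 0.91, SE 0.16), and 1 fall, the NF-kB subunit gene Relb (-0.51, SE 0.13; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0389, and 0.141 without unstimulated wild-type 3), the same counts when adjusted over the list alone (camera adjusted p = 0.722). No interferon-stimulated gene passed (camera adjusted p = 0.862), with Trim30a at log2 -1.13 (SE 0.34, edgeR adjusted p = 0.0886) and Ifit1 at -0.14 (SE 0.52). No TLR9 and nucleic acid sensing gene passed (camera adjusted p = 0.862), with the protease gene Ctss, which cleaves endosomal receptors, at log2 -0.94 (SE 0.29, edgeR adjusted p = 0.0889), Tlr9 at -0.11 (SE 0.24) and Unc93b1 at -0.07 (SE 0.11).

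Rab27 effector and exocytosis genes gave 2 rises and 1 fall among 18 (adjusted over the list alone, 3 rose and 2 fell, camera adjusted p = 0.862; median 0.00 and mean -0.03, with the test pointing up). Madd was 1.4-fold higher (log2 0.48, SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0245, and 0.145 without unstimulated knockout 2), and the secretory GTPase gene Rab37 was 1.55-fold lower (-0.63, SE 0.16, edgeR adjusted p = 0.0371, and 0.161 without unstimulated wild-type 1). No endolysosomal trafficking gene passed (camera adjusted p = 0.173), with the late endosome GTPase gene Rab7 at log2 0.36 (SE 0.13). Receptor genes gave 3 rises and 2 falls (adjusted over the list alone, the same counts, camera adjusted p = 0.862), with Cd14 1.93-fold higher (log2 0.95, SE 0.22, edgeR adjusted p = 0.0206, and 0.0905 without unstimulated knockout 2). Stress response genes gave 1 rise and 3 falls (adjusted over the list alone, 1 rose and 4 fell, camera adjusted p = 0.173). Antigen presentation genes gave 1 rise, the costimulator gene Cd86 (log2 0.96, SE 0.24, edgeR adjusted p = 0.033, and 0.157 without unstimulated knockout 1; adjusted over the list alone, 1 rose, camera adjusted p = 0.898; mean 0.04, with median -0.06 and the test pointing down). Lipid mediator genes gave 1 rise and 1 fall (adjusted over the list alone, 1 rose and 4 fell, camera adjusted p = 0.438), the fall being the thromboxane synthase gene Tbxas1 (log2 -1.02, SE 0.21, edgeR adjusted p = 0.014, and 0.0766 without unstimulated wild-type 1). Fry, run beside camera, called the lipid mediator list lower (fry adjusted p = 0.0374).

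In unstimulated cells no primary granule gene passed between the genotypes (camera adjusted p = 0.862), with the cell cycle regulator gene Rgcc at log2 -0.85 (SE 0.29) and Mpo at -0.02 (SE 0.71), where the knockout libraries spread widely (103 ± 107 against 104 ± 16.8 CPM). No secondary or tertiary granule gene passed (camera adjusted p = 0.722), with the collagenase gene Mmp8 at log2 -0.38 (SE 0.20) and Mmp9 at -0.33 (SE 0.23). No NADPH oxidase gene passed (camera adjusted p = 0.807), with Ncf1 at log2 -0.28 (SE 0.15). No apoptosis gene passed (camera adjusted p = 0.453; adjusted over the list alone, 1 rose and 1 fell), with the death effector gene Bak1 at log2 -0.57 (SE 0.17). No cell cycle gene (camera adjusted p = 0.722) and no glycolysis and hypoxia gene passed (camera adjusted p = 0.862).

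The count of genes differing in unstimulated cells fell to 328 and 324 without unstimulated wild-type 1 or 3, and to 311 and 278 without unstimulated knockout 1 or 2. Without both knockout libraries numbered 1 it was 341. DESeq2 called 748, 388 higher and 360 lower.

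With CpG the knockout differed from wild-type cells in 423 genes, 184 higher and 239 lower, 233 of them by at least 2-fold. Il12b was 4-fold higher, at 34.6 ± 5.3 against 8.63 ± 4.95 CPM (log2 2.00, SE 0.33), and Il18 2.84-fold higher (log2 1.51, SE 0.27). Hmox1 was 1.8-fold lower (log2 -0.85, SE 0.14). Adjusted p was 0.00252 for Il12b, 0.00492 for Il18 and 0.00202 for Hmox1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

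At the same limit of 5 CPM, the highest with CpG were Trim34b (log2 5.48, SE 0.33), Cd3d (4.77, SE 0.30), Hal (4.34, SE 0.32), the adaptor-family gene Plekhs1 (3.94, SE 0.18) and the lipid phosphatase gene Inppl1 (3.39, SE 0.22). Among the lowest were Zbtb44 (at least 136-fold lower), Trim12a (log2 -9.99, SE 0.37), Eps8l1 (233 times lower, interval 64.1 to 1930), the dynein light chain gene Dynlt1b (log2 -6.98, SE 0.34) and Hbb-bt (-6.95, SE 0.61). Dynlt1b too has near-identical copies and is uncertain. Between the unstimulated and the CpG comparison, which share no library, 105 genes were higher in both (3.9 expected by chance) and 187 lower in both (6.3 expected), and 1 gene was called in opposite directions. The chance counts assume independent comparisons, whereas same-numbered libraries of a genotype correlate between treatments (r from 0.09 to 0.68), so differences between single animals would recur in both. Their log2 fold changes correlated at r = 0.79 across genes, which are not independent replicates.

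NF-kB genes were higher in the CpG-treated knockout, with 5 rises among 29 (adjusted over the list alone, 11 rose and 1 fell, camera adjusted p = 2.86e-07, and adjusted p = 0.377 with an estimated correlation). They included the NF-kB inhibitor gene Tnip1 (log2 0.89, SE 0.15) and Sod2 (0.67, SE 0.12). Interferon-stimulated genes gave 2 rises, with 35 of 36 estimates positive (adjusted over the list alone, 2 rose, camera adjusted p = 1.7e-06, and adjusted p = 0.621 with an estimated correlation). These were the guanylate-binding protein gene Gbp5 (log2 2.02, SE 0.48) and Parp14 (0.93, SE 0.24), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0323 and 0.0479. Ifit1 did not pass (log2 0.98, SE 0.46, edgeR adjusted p = 0.279).

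TLR9 and nucleic acid sensing genes gave 2 rises with CpG (adjusted over the list alone, 2 rose, camera adjusted p = 0.296): the DNA sensor gene Cgas (log2 0.80, SE 0.20) and Irf5 (0.43, SE 0.11), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0383 and 0.0408. Cgas, like Il18, lies within 200 tested genes of Rab27a in the gene order. Tlr9 did not pass (log2 0.15, SE 0.21). Without wild-type CpG 1 the edgeR adjusted p was 0.141 for Gbp5, 0.236 for Parp14, 0.204 for Cgas and 0.236 for Irf5.

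Cytokine genes gave 2 rises, Il12b and Il18 (adjusted over the list alone, 2 rose, camera adjusted p = 0.00446, and adjusted p = 0.408 with an estimated correlation). Tnf (log2 0.31, SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.142), Il1b (0.47, SE 0.20, edgeR adjusted p = 0.227) and Il6 (0.78, SE 0.49) did not pass. Of the chemokine genes none passed (adjusted over the list alone, 2 rose and 1 fell, camera adjusted p = 0.484), with Ccl5, a lymphocyte attractant gene, at log2 1.29 (SE 0.35, edgeR adjusted p = 0.0609), Cxcl2 at -0.42 (SE 0.14) and Ccl3 at 0.03 (SE 0.17).

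Stress response genes gave 4 falls and no rise (adjusted over the list alone, 5 fell, camera adjusted p = 0.00446, and adjusted p = 0.377 with an estimated correlation). Lipid mediator genes gave 1 fall, Tbxas1 (log2 -1.28, SE 0.22; adjusted over the list alone, 3 fell, camera adjusted p = 0.137). Fry, run beside camera, called this list lower (fry adjusted p = 0.00909). Apoptosis and survival genes gave 2 rises (adjusted over the list alone, 2 rose, camera adjusted p = 0.0562), and fry called this list higher (fry adjusted p = 0.0162). One of the rises was the survival kinase gene Pim1 (log2 0.57, SE 0.12; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0162, and 0.114 without wild-type CpG 1). NADPH oxidase genes gave 1 rise, Cybb, at 1710 ± 113 against 1140 ± 93.8 CPM (log2 0.58, SE 0.13, edgeR adjusted p = 0.0189, and 0.146 without wild-type CpG 1; adjusted over the list alone, 1 rose, camera adjusted p = 0.239). The primary granule list gave 1 fall, that of the cell cycle regulator gene Rgcc (log2 -1.19, SE 0.29, edgeR adjusted p = 0.0347, and 0.167 without knockout CpG 2; adjusted over the list alone, 1 fell, camera adjusted p = 0.425). The other 10 members of that list did not pass. The myeloid receptor gene Csf1r, counted with the monocyte markers, was 1.55-fold higher (log2 0.63, SE 0.12, edgeR adjusted p = 0.00986, and 0.0642 without wild-type CpG 1).

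The remaining lists held no gene that passed with CpG. Camera adjusted p was 0.61 for receptor genes, with the bacterial sensor gene Nod2 at log2 0.79 (SE 0.23), and 0.73 for Rab27 effector and exocytosis genes (median 0.06, mean -0.02), with Rab37 at -0.49 (SE 0.16). It was 0.474 for endolysosomal trafficking genes, with the granule tetraspanin gene Cd63 at log2 -0.47 (SE 0.16), and 0.399 for secondary and tertiary granule genes, with Hp at 0.44 (SE 0.18). For cell cycle genes it was 0.885 (median 0.00, mean -0.02), for glycolysis and hypoxia genes 0.123, for immediate early genes 0.202 and for antigen presentation genes 0.137.

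DESeq2 called 716 genes with CpG, 404 higher and 312 lower, and scaling by library size alone gave 155 higher and 314 lower. A fit of these 6 libraries alone called 253, the count was 234 without wild-type CpG 1 and 699 without knockout CpG 3, and without both knockout libraries numbered 3 it was 824.

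Of the 200 tested genes nearest to Rab27a in gene order (100 on either side in the mouse assembly GRCm38.p6), 20 were called in a genotype comparison, 10% against 5.8% elsewhere (odds ratio 1.82, interval 1.08 to 2.92; two-sided Fisher's exact test, p = 0.0207). With 50 genes on either side the odds ratio was 0.847 (Fisher's exact test, p = 1) and with 200 it was 2.41 (exact p = 3.07e-07). This test was chosen after the data were seen, and it treats genes as independent although genotype calls cluster along the whole gene order, so its intervals are too narrow and its p-values too small.

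Markers of other marrow cells varied between the knockout libraries. Summed erythroid markers were 444, 1846 and 6058 CPM in unstimulated knockout libraries 1, 2 and 3, and 528, 1683 and 6137 with CpG, against 4007 to 5265 in wild-type cells. Erythroid markers gave 1 fall among 10, Hbb-bt, in both genotype comparisons (adjusted over the list alone, 1 fell in each). Hbb-bt was low in every unstimulated knockout library, also in number 3, whose erythroid sum was the highest. A low erythroid sum therefore does not account for its low level there. Whether Hbb-bt varied with that sum among the knockout libraries was not tested. It lies in a run of neighbouring genes called between genotypes. In unstimulated cells the list had a median of -0.38 and a mean of -1.23 log2 units. Camera adjusted p was 0.0305 in unstimulated cells (0.999 with an estimated correlation) and 0.0605 with CpG. B cell marker sums were 7.65, 32 and 98.5 CPM in the unstimulated knockout, and no B cell gene passed. T and NK cell markers gave 1 rise among 6, Cd3d, which also lies in a run of neighbouring genes called between genotypes. Their sums were 84.8 to 158 CPM in the knockout and 9.04 to 15.1 in wild-type cells. Their camera adjusted p was 0.114 in unstimulated cells (median -0.24, mean 0.44) and 0.00948 with CpG (0.192 with an estimated correlation).

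The platelet gene Pf4 was 3.89-fold lower in unstimulated knockout cells (log2 -1.96, SE 0.51; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0421, and 0.192 without unstimulated wild-type 3). Of the monocyte and macrophage markers none passed in unstimulated cells (adjusted over the list alone, 4 fell, camera adjusted p = 0.114) and 1 rose with CpG (camera adjusted p = 0.964; median 0.21, mean -0.11). Y-linked Kdm5d and Ddx3y were present in all 4 groups, at 18.3 and 61.7 CPM in unstimulated wild-type cells. Y-linked Eif2s3y was 1.98-fold lower in the unstimulated knockout (log2 -0.98, SE 0.17) and 1.9-fold lower with CpG (-0.92, SE 0.17). As a list the genes of the sex of the animals had a camera adjusted p of 0.988 (1 fall among 4) and 0.964 with CpG (1 rise and 1 fall). Mature neutrophil marker sums lay between 66370 and 80730 CPM in wild-type libraries and between 47220 and 79820 in knockout libraries, of which 3 lay below the whole wild-type range. Camera adjusted p for mature neutrophil, B cell, plasma cell, eosinophil, dendritic cell, megakaryocyte and progenitor markers was at least 0.271 in unstimulated cells and 0.513 with CpG. Fry, run beside camera, called the 3 megakaryocyte and platelet markers lower in the knockout (fry adjusted p = 0.000101 without CpG and 0.00107 with it). Median, mean and test differed in sign for B cell markers in both genotype comparisons, where the median was 0.40 and 0.41 and the test pointed down. They also differed for neutrophil and plasma cell markers with CpG and for the sex genes without it, and, for the CpG effect, for T cell markers in wild-type cells, B cell and neutrophil markers in the knockout and eosinophil markers in both genotypes.

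**Figure D3:**
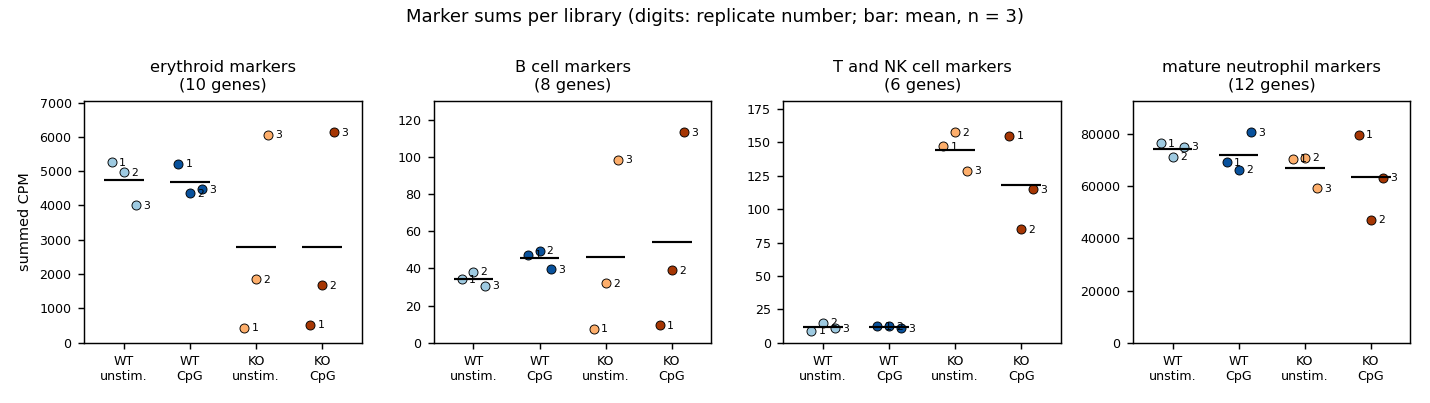
Summed CPM of erythroid, B cell, T and NK cell and mature neutrophil markers per library in the 4 groups (digits: replicate number, bar: mean of 3). Erythroid sums run from 444 to 6058 CPM across the unstimulated knockout libraries, and T and NK cell sums are higher in all knockout libraries through Cd3d.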

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

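The tests of scaling, of the response of other cells and of low baseline in this part were chosen only after the larger response in the knockout had been seen. Across 537 CpG-responsive genes the median response was 0.38 log2 units larger in the knockout, and scaling of the libraries is an unlikely whole cause, because library size alone still gave 0.332. Larger differences in genes of low baseline are unlikely to be the whole cause too, since genes with at least 5 CPM gave 0.418. A response of other cells carried along cannot be told apart from a difference in the neutrophils: the knockout pair numbered 1, lowest in erythroid and B cell genes, had a median response of 1.285, within the 1.124 to 1.312 of wild-type pairs, but number 2, also low in erythroid genes, had 1.583 and number 3, the highest in them, 1.575. A stronger CpG response through loss of Rab27a could also give this pattern. In edgeR 0 single-gene interactions passed without a block. With animal as a block 13 passed, 6 with positive and 7 with negative estimates. In the 10 splits of numbered pairs between genotypes the real one gave 0.377 and the highest other 0.26, too few splits for a share under 0.05.

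In the interaction of genotype and CpG, camera gave an adjusted p of 1.59e-15 for interferon-stimulated genes, with 36 of 36 estimates positive and a median of 0.72 log2 units (adjusted p = 0.306 with an estimated correlation). NF-kB pathway and feedback genes had a camera adjusted p of 9.72e-11, with 25 of 29 positive and a median of 0.35 (0.306 with an estimated correlation). Camera adjusted p was 0.00191 for lower immediate early genes and 0.00441 for lower chemokine genes (both 0.306 with an estimated correlation). It was 0.00441 for higher NADPH oxidase genes, 0.00893 for higher antigen presentation genes and 0.026 for higher TLR9 and nucleic acid sensing genes (all 0.306 with an estimated correlation). Glycolysis and hypoxia genes were higher at 0.00393 (0.514 with an estimated correlation), and secondary and tertiary granule genes at 0.00609 (0.428). The other function lists had camera adjusted p of at least 0.0859 and the marker lists of at least 0.072, and fry called no list. In exact permutations of the responses of list sums, 8 of the 18 function lists reached p = 0.1, the smallest possible, all higher in the knockout. They were NF-kB (0.33 log2 units), NADPH oxidase, glycolysis, antigen presentation, secondary granule and TLR9 genes, and also cell cycle and other receptor genes, which camera did not call. Interferon-stimulated genes (0.60, exact p = 0.3), chemokine genes (-0.089, exact p = 0.8) and immediate early genes (-0.105, exact p = 0.5) overlapped between the genotypes.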

How the results depend on the processing

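For 257 named gene results 6124 alternative values were computed, of which 5832 kept direction and call and 0 reversed, while 62 uncalled values changed sign. Of 435 alternative list tests 374 were the same and 0 reversed. Of 40 list calls 8 held with an estimated correlation, 23 by fry and 37 with replicate number as a block. The planned test of genes within 10 Mb of Rab27a (5 and 20 Mb as alternatives) was not run, because the annotation used is of another build than the counts. The tests by gene order and the fits without knockout pairs were chosen after seeing the data.

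The CpG count in wild-type cells was 652, with 316 at a 2-fold threshold and 425 to 758 leaving out single libraries. In the knockout it was 1257, with 553 at 2-fold and 818 to 1347 leaving out single libraries. The genotype count without CpG was 513, with 268 at 2-fold, 278 to 604 leaving out single libraries and 341 without both knockout libraries numbered 1. With CpG it was 423, with 716 in DESeq2, 253 with only the libraries compared, 233 at 2-fold, 234 to 699 leaving out single libraries and 824 without both knockout libraries numbered 3. The interaction count was 0, also without any single library, and 2 in DESeq2. The 2-fold counts are lower by construction; the cause of the other shifts was not tested.

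The median response was larger in the knockout by 0.377 log2 units, by 0.47 for genes chosen by the knockout CpG effect alone, by 0.328 for genes chosen by the wild-type CpG effect alone (there -0.025 for the lowered genes), by 0.31 to 0.494 leaving out single libraries and by 0.441 without both knockout libraries numbered 1. Near Rab27a the odds ratio of 1.82 for 100 genes on either side was 0.847 for 50.

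With animal as a fixed block in edgeR the CpG counts were 1824 in wild-type cells and 2591 in the knockout (1380 higher and 1211 lower). In that fit 13 interactions were called, 6 positive and 7 negative. Among the positive ones were Alas1 (log2 1.02, edgeR Benjamini-Hochberg adjusted p = 0.0408) and Il18bp (0.87, 0.0408). In the knockout, where the pairing threshold was missed although every library correlated best with its own number in both genotypes, blocking added Il6 (adjusted p = 0.0119), Cd79a (0.00123) and H2az1 (0.000732). With replicate number as a block in camera the stress response list there went from 0.13 to 0.0421. In wild-type cells animal as a block also added Blnk (0.0051), Cd8a (0.046), Siglecf (0.0202) and H2az1 (0.0267), and changed no further call of a named gene beyond Madd, Gusb and Unc93b1. Between unstimulated genotypes blocking by number added Ctss (0.0136), Rab7 (0.0443) and Rgcc (0.0263), the chemokine list went from 0.0365 to 0.0526 with replicate number as a block, Relb to 0.0914 and Pf4 to 0.0771 with animal as a random block in limma (consensus correlation 0.488). With CpG, Parp14 went to 0.0873 with that block, and number as a block added Ccl5 (0.0397) and Nod2 (0.0192) and took the erythroid list from 0.0605 to 0.0156. In the interaction it took the monocyte list from 0.072 to 0.043.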

Other observations

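Many genes that differed between the genotypes in both treatments stood beside each other in the gene order of GRCm38.p6. In one run of neighbours, the TRIM-family restriction factor genes Trim12a (log2 -9.39), Trim5 (-4.23) and Trim6 (-2.70) were lower in unstimulated knockout cells, as were the IL-18 antagonist gene Il18bp (-2.01) and the lysosomal adaptor gene Lamtor1 (-0.56), while Trim34b was higher (4.89). In another, the chaperone gene Hyou1 was lower (-2.85), and Cd3d (4.91), the adhesion genes Mpzl2 (1.98), Mpzl3 (1.46) and Jaml (0.92) were higher. In another, the acyltransferase gene Mogat2 (-3.35), the myosin gene Myo7a (-1.22) and the ubiquitin ligase gene Rnf169 (-0.97) were lower. All of these also differed between the genotypes with CpG, in the same direction, because only genes called so in both treatments were listed. Windows of 20 tested genes held up to 8 genes called in both treatments, against at most 7 in 1000 permutations of the order. Trim12a, Trim34b and Hbb-bt, which lies in the first run, have near-identical copies and are uncertain.

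Of the genes named between genotypes, Il18, Cd3d, Cgas and Alas1 are among the 200 tested genes on either side of Rab27a, as are Hyou1, Mpzl2, Mpzl3 and Jaml of the run that holds Cd3d.

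The tests of gene order, of unselected cells, of depth and of genotype in this part were chosen only after the patterns had been seen. Of 629 genes called between genotypes, 403 had a called gene among their 5 nearest on either side, against a median of 283 and a highest of 332 in 1000 permutations, while CpG calls did not cluster (969 against 962). Chromosome blocks of another strain in one of the lines could give such runs. The count of 403 only restates the clustering and cannot decide this, and strain variants were not examined. Flanking sequence kept around Rab27a is an unlikely whole cause, as 4% of the clustered genes lie within 100 genes of it and 10.2% within 200. The 403 include genes that have a called neighbour by chance (median 283), so these shares understate the part near Rab27a. Cells that vary between the knockout samples as erythroid cells do cannot be told apart from such blocks. This was measured among clustered genes called without the knockout pair numbered 3, nearest to wild-type in erythroid genes. Their median change in that pair was 65.6% of the mean of the others, and genes called on few libraries overstate their change in them. Reads shared between paralogs are unlikely too, as 333 genes still clustered once those sharing a name root with a neighbour were left out (highest in permutations 264).

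Knockout libraries of different number differed in erythroid, B cell and early granule genes. From number 1 to number 3, without and with CpG, erythroid sums rose 13.6 and 11.6 times, B cell sums 12.9 and 11.9 times and early granule sums (Mpo, Elane, Prtn3 and Ctsg) 13 and 8.4 times. Sequencing depth is an unlikely cause, with a depth ratio of 0.994. Different amounts of unselected marrow cells cannot be told apart from other causes. Outside these genes, 28 markers of other marrow cells at 1 to 10 CPM in wild-type cells rose a median of 4.41 times (quartiles 1.59 and 8.44) without CpG and 2.48 times (1.28 and 6.2) with it. Sums of eosinophil (2.02 and 2.61 times) and plasma cell markers (1.79 and 1.59) rose in both treatments, and that of monocyte markers only without CpG (1.97 and 0.908). Dendritic cell (1.12 and 1.14), megakaryocyte (0.99 and 1.11) and progenitor sums (0.957 and 0.822) moved less, and T and NK cell sums were lower (0.875 and 0.743). The T and NK cell sum was high in all knockout libraries through Cd3d, so its ratio is mostly that of Cd3d. With CpG the monocyte sum consisted largely of Csf1r. These ratios therefore say little about the amounts of those cells. The progenitor sum was already 2320 to 2610 CPM in wild-type libraries, a level at which added cells would show little. The knockout numbers share the same genotype, so genotype alone cannot set them apart from each other. Whether it lowers erythroid genes cannot be told either. Numbers 1 and 2 lie below the 95% prediction interval from the wild-type numbers (2775 to 7947 CPM). Number 3, a single pair with a mean erythroid sum of 6097 CPM, lies inside it.

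Among the 10 splits of the 6 libraries of a comparison, the real one called the most genes in each of the first 4, which is 1 of 10 and too few for a share under 0.05. In wild-type cells it called 652 and the highest other split 0, in the knockout 1257 and 129, between unstimulated genotypes 513 and 0, and with CpG 423 and 0. For the interaction the real count was 0, so all 100 relabelings drawn, the real one among them, call at least as many by construction and decide nothing. The highest called 1322, and the structure of the samples it points to is the genotype difference itself, because exchanging the genotypes of the CpG libraries alone turns the interaction into the sum of both genotype effects.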
